A study of Gallus gallus with 41 samples.

How the data were processed

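Single cells were taken from chick retinas at 8 embryonic ages. Per the labels' protocols, retinas were dissociated with papain and cells were drawn into a pulled glass pipette without culture. RNA was reverse transcribed from an oligo dT primer, the cDNA was tailed with terminal transferase and amplified over 35 PCR cycles with the same primer. The product was fragmented with DNase I, labelled with biotin and put on an Affymetrix chicken array, 1 cell to an array. Priming from the poly(A) tail and many PCR cycles favour the 3′ ends of transcripts and widen differences in yield between cells, so a low signal in a cell does not show that the transcript was absent.

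The authors deposited log2 values of 38535 probe sets for 41 cells, made with MAS5 per the submitters' processing notes, in a version not given in the sources used here. The deposited log2 values ran from -4.27 to 22.37 and 0 were missing. The trimmed mean of the linear signal, with 2% taken off each end, lay between 500 and 500.2 on each array, and no further scaling was applied. All 41 columns were matched to samples by their labels and 0 columns of sample values were left unused. Arrays give no counts, so no depth can be stated and the number of cells limits the precision.

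Genes were named through the platform annotation supplied with the data: 27178 probe sets had 1 symbol, 177 had several and 11180 had none. Of those with 1 symbol, 26863 matched by gene ID in RefSeq genes of the assembly GRCg7b, and 0 symbols were updated. No coordinates are given, since the probe sets' build is not given in the sources used here. A gene with several probe sets was read from the probe set with the highest mean over the 41 cells, and the mean of all its probe sets was an alternative. The 96 control probe sets were left out. A further 689 probe sets were designed on other sequence records than chicken genes and stayed in the pool of tested probe sets. Their 95th percentile on each array served as a measure of background.

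Each cell was placed at the age in its title. E6 replicate 1 carries E5 in its source name and was kept at E6, with its move to E5 and its removal as alternatives. The series text speaks of 39 cells. The labels name no embryo, so each time point counted as 1 sample and cells were not used as replicates. Standard deviations over cells describe their spread and enter no test.

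The only tested contrast was the slope per embryonic day. Linear signals were floored at the median of the whole table (log2 5.00) and put back on the log2 scale. Probe sets at or above the 80th percentile of their array in at least 3 cells were kept. The 8 time point means, weighted by their cells, were fitted on day with limma (lmFit, and eBayes with a trend), which left 6 residual degrees of freedom. P-values were adjusted with the Benjamini-Hochberg method and called under 0.05. They measure the spread of 8 time point means around a straight line, which may be technical. That spread was moderated toward a trend over all tested probe sets, with 78.4 prior degrees of freedom against the 6 residual ones. The p-values thus rest mostly on variance pooled over probe sets, which are not independent, and less on the scatter of each gene. In a self-test the values of each of 24981 probe sets were shuffled over the cells and known slopes were added to some. There limma recovered 34% of 50 probe sets with a slope of 0.2 per day, 84% at 0.4, 84% at 0.6 and 100% at 0.8, with 9 false calls. Shuffling single cells removes what the cells of a time point share, so these figures hold only without such structure and are likely too favourable.

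In all, 21 gene lists were tested on the slope with camera at a preset inter-gene correlation of 0.01, and again with a correlation estimated from the residuals. Camera compares a list with all other genes; fry tests whether the genes of a list move, on balance, in the same direction. The lists were cell cycle, retinal progenitor, neurogenic, ganglion cell, amacrine, horizontal, photoreceptor, bipolar, Muller glia, synapse, early neuron cytoskeleton, housekeeping, dissociation stress, pigment epithelium, lens, erythroid, microglia, vascular and mesenchymal, oligodendrocyte, ribosomal protein and mitochondrial respiration.

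The steps from E3 to E6, E6 to E9 and E9 to E14, the detection of listed genes, the clusters and the similarity of cells have no test. A gene counted as detected in a cell at or above the 80th percentile of that array. Shares of cells carry exact Clopper-Pearson intervals at the 95% level, which cover counting error only. The genes named in the steps were chosen for the difference in these shares, so their intervals do not keep that level. For each list the median difference was placed among 10000 random lists of the same size, matched on mean expression. Cells were clustered on the 1000 most variable probe sets (1 minus Pearson correlation, average linkage) into 6 clusters. A cluster took a cell type name where at least 3 markers of a list stood among its 50 leading genes. No doublet caller was run, since each cell was picked by hand.

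Named genes followed a rule. For the slope these were the 12 steepest called genes in each direction, filled up with the genes of smallest unadjusted p, given as values. For each list they were members past the threshold, at most 6, or the 3 members with the highest mean. For each step they were the 5 genes in each direction with the largest difference in the share of cells detected. Clusters were described by their 5 leading genes. Groups, tests, lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives changed the floor, the scaling, the filter, the weights, the time scale, the labels of single cells, the detection level and the clustering, and left out each time point and each cell in turn. Alternatives without 6 arrays of high background, without 2 arrays that share a profile, with a floor at the highest background and with detection as the response were added after seeing the data.

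Tools were R 4.3.3 with limma 3.58.1 and data.table (1.17.8), and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.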

Results

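The data hold expression profiles of 41 single cells from dissociated embryonic chick retinas. Embryonic day 3 (E3) gave 6 cells, E4 3, E5 5, E6 10, E7 1, E9 6, E14 8 and E15 2. The series follows how the transcripts of individual retinal cells differ over these ages, which span the production of most retinal neurons. Values are log2 MAS5 signals, and the cells of a time point count as 1 sample, since no embryo is named. Array medians ran from log2 3.90 to 7.87. The 3 E4 arrays, E6 replicate 7 and both E15 arrays had medians of 7.47 ± 0.39 (SD, n = 6) against 4.67 ± 0.45 (SD, n = 35) on the other arrays, and are called arrays of high background. ACTB, cytoskeletal actin, has probe sets at both ends of its transcript. Its 3′ signal exceeded its 5′ signal by 6.65 ± 1.99 log2 units at E3 (SD, n = 6), 1.95 ± 1.55 at E6 (n = 10), 1.26 ± 0.54 at E9 (n = 6) and 3.08 ± 0.80 at E14 (n = 8).

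The first comparison asked which genes moved with embryonic day. ENO2, the neuronal form of the glycolytic enzyme enolase, rose by 0.91 ± 0.17 log2 units per day (SE, 8 time points; limma adjusted p = 0.00526). Its mean signal was 5.15 at E3, 9.07 at E6, 14.82 at E9 and 16.12 at E14, and it was detected in 1 of 6, 6 of 10, 6 of 6 and 8 of 8 cells. RELN, which encodes the secreted glycoprotein reelin, rose by 0.80 ± 0.17 per day (adjusted p = 0.0187), from a mean of 5.32 at E3 to 15.07 at E14. NEFH, the heavy neurofilament subunit of axons, rose by 0.67 ± 0.14 (adjusted p = 0.0187), and was detected in 2 of 10 cells at E6 and 8 of 8 at E14. SNCB (beta-synuclein) rose by 0.75 ± 0.16 and RPH3A (rabphilin, a synaptic vesicle protein) by 0.61 ± 0.14 per day.

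Other called genes were CADM2, a cell adhesion molecule (0.72 ± 0.16 per day), HS3ST2, a heparan sulfate sulfotransferase (0.70 ± 0.14), and PPEF1, a protein phosphatase (0.70 ± 0.15). MME, the peptidase neprilysin, rose by 0.65 ± 0.13, ELMOD1 by 0.56 ± 0.13, PURG, a nucleic acid binding protein, by 0.49 ± 0.12 and LOC100859665 by 0.49 ± 0.10. The single E7 cell was at the floor for ENO2, RELN and SNCB. Both E15 cells, on arrays of high background, lacked detection of NEFH, RPH3A, ELMOD1 and MME. Among these named genes the E15 mean lay above the E14 mean only for RELN (18.10 against 15.07) and CADM2 (14.67 against 13.05). It lay below for the others, such as ENO2 (13.60 against 16.12) and NEFH (8.58 against 13.18), so a slope is not a steady rise. No gene fell past the threshold. Among those with the smallest unadjusted p, NES, the progenitor intermediate filament nestin, had a slope of -0.63 ± 0.18 and means of 14.60 at E3 and 6.14 at E6. HMGN1, a nucleosome binding protein, had -0.57 ± 0.17, IDI2, an isoprenoid isomerase, -0.56 ± 0.16, RNH1, a ribonuclease inhibitor, -0.54 ± 0.17 and ASF1A, a histone chaperone, -0.51 ± 0.17. STK4 had -0.49 ± 0.16, HSPA4 -0.49 ± 0.16, HNRNPM -0.46 ± 0.12, HJURP, a centromere histone chaperone, -0.45 ± 0.15, RPL3 -0.45 ± 0.14, VIM, the intermediate filament vimentin, -0.41 ± 0.12 and PTS -0.38 ± 0.13.

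Of 24981 probe sets tested with limma, 33 rose and 0 fell at an adjusted p under 0.05, and 17 of the 33 carry a gene symbol. At an unadjusted p under 0.05 there were 880 rising and 291 falling. The count was 0 with no floor, after quantile normalization, after scaling to a common 75th percentile, with equal weights, without the arrays of high background and without E4. It was 6 without E3, 21 without E5, 104 without E6, 16 without E7 (the removal of E7 replicate 1), 77 without E9 and 9 without E14. Leaving out a single cell gave 52 without E6 replicate 4, 51 without E9 replicate 6, 16, 17, 18, 17 and 16 without E14 replicates 1, 2, 6, 7 and 8, 70 without E15 replicate 3, 67 without E15 replicate 2 and 50 without E4 replicate 1.

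**Figure D1:**
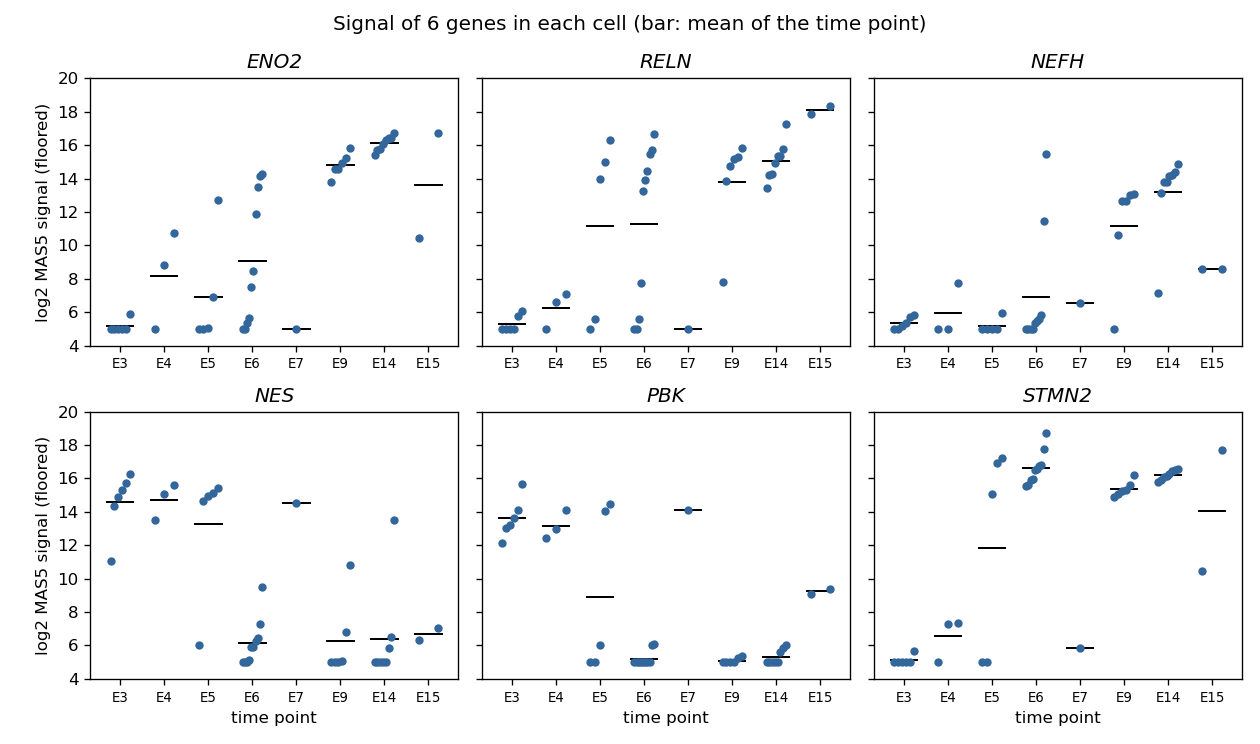
Floored log2 MAS5 signal (vertical axis) of 6 genes in each of the 41 cells by time point (horizontal axis), with a point per cell and a bar at the mean of the time point. ENO2, RELN and NEFH have higher means at E14 (16.12, 15.07 and 13.18) than at E3 (5.15, 5.32 and 5.35), NES and PBK are near the floor in most cells from E6 on apart from the E7 cell, and STMN2 is high in every E6, E9 and E14 cell.

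With the preset inter-gene correlation, camera separated lists of cycling genes from lists of neuronal genes. The correlation estimated from the residuals was far above the preset value. It was 0.605 for the cell cycle, 0.212 for the ganglion cell, 0.206 for the synapse and 0.437 for the early neuron cytoskeleton list. With the estimated values these lists were not called, so the small camera p-values below depend on the preset. The cell cycle list fell with day (camera adjusted p = 9.25e-19), with a median slope of -0.28 and negative slopes in 30 of 33 genes; the list has adjusted p = 0.544 with an estimated correlation. Of its members 0 were called adjusted over the list alone, with 16 falling at an unadjusted p under 0.05 in limma. RRM1, a subunit of ribonucleotide reductase, had a slope of -0.49 ± 0.17, CCNA2 (cyclin A) -0.17 ± 0.17 and KIF20A, a mitotic kinesin, 0.08 ± 0.17. The ganglion cell list rose (camera adjusted p = 8.25e-08), with a median slope of 0.30 and positive slopes in 17 of 18 genes; it has adjusted p = 0.544 with an estimated correlation. Adjusted over the list alone, 6 members rose and over all genes 0 did. These were STMN2, a microtubule regulator of growing axons (0.67 ± 0.18), NEFM, the medium neurofilament subunit (0.47 ± 0.18), SNCG (0.47 ± 0.16), RBPMS2 (0.45 ± 0.17), ELAVL4, a neuronal RNA binding protein (0.44 ± 0.18), and THY1 (0.43 ± 0.12).

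The synapse list rose (camera adjusted p = 0.000674, median slope 0.09, 15 of 19 genes positive), with adjusted p = 0.544 with an estimated correlation. Adjusted over the list alone, 4 of its members rose and 0 over all genes: SNAP25, a part of the vesicle fusion machinery (0.65 ± 0.17), CPLX3, a complexin of ribbon synapses (0.59 ± 0.15), and the vesicle proteins SV2B (0.40 ± 0.13) and SV2C (0.30 ± 0.11). The early neuron cytoskeleton list, which shares STMN2, NEFM and NEFL with the ganglion cell list, rose as well (camera adjusted p = 0.00259, median slope 0.17, 15 of 18 genes positive), with adjusted p = 0.813 with an estimated correlation. Adjusted over the list alone, 4 of its members rose: STMN2, NEFM, the kinesin KIF5C (0.51 ± 0.17) and CRMP1 (0.39 ± 0.12). Its call ended without E3 (adjusted p = 0.659), without E4 (adjusted p = 0.178), without E14 (adjusted p = 0.125), with equal weights (adjusted p = 0.186), after scaling to a common 75th percentile (adjusted p = 0.0537) and with a floor at the highest background (adjusted p = 0.0830).

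The ribosomal protein list fell (camera adjusted p = 4.92e-11), with a median slope of -0.09 and negative slopes in 56 of 67 genes, and has adjusted p = 0.544 with an estimated correlation. Its most abundant members RPS3A, RPS6 and RPS15A had slopes of -0.04 ± 0.07, -0.04 ± 0.08 and -0.01 ± 0.08. Mitochondrial respiration fell (camera adjusted p = 0.00901, median slope -0.05, 46 of 72 genes negative) and has adjusted p = 0.863 with an estimated correlation; COX4I1 had 0.04 ± 0.09, ATP5C1 -0.18 ± 0.13 and ATP5F1AZ -0.07 ± 0.11. The retinal progenitor list fell (camera adjusted p = 0.0120, median slope -0.07, 11 of 16 genes negative) and has adjusted p = 0.813 with an estimated correlation. PAX6, an eye field transcription factor, had 0.07 ± 0.14, DKK3 0.15 ± 0.18 and SIX6 0.04 ± 0.13. The counts adjusted over the list alone were 0 for these 3 lists. At an unadjusted p under 0.05 limma had 7, 2 and 1 falling members and 0, 2 and 0 rising ones. Without the arrays of high background the adjusted p was 0.590 for mitochondrial respiration and 0.205 for the retinal progenitor list. Mitochondrial respiration also lost its call without E3 (adjusted p = 0.659), E15 (adjusted p = 0.682), E15 replicate 3 (adjusted p = 0.113) or E15 replicate 2 (adjusted p = 0.106). It ended as well with no floor (adjusted p = 0.0857), with a floor at the 25th percentile (adjusted p = 0.0514), after quantile normalization (adjusted p = 0.0985) or scaling to a common 75th percentile (adjusted p = 0.110), for late against early ages (adjusted p = 0.438) and without the 2 cells of later accession (adjusted p = 0.120). The progenitor list lost its own without those 2 cells (adjusted p = 0.0575), without E4 (adjusted p = 0.0930) or E15 (adjusted p = 0.146). With detection as the response, the ribosomal protein, progenitor and early neuron cytoskeleton calls ended at an adjusted p of 0.0518 and mitochondrial respiration at 0.0742. With an estimated correlation 0 of the 7 camera calls hold. Fry called none of these 7 lists in 1 direction, with p = 0.0525 for ganglion cell, 0.0542 for synapse and 0.157 for cell cycle genes. For ribosomal protein, early neuron cytoskeleton, retinal progenitor and mitochondrial respiration its p was 0.185, 0.331, 0.550 and 0.616.

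The other 14 lists were not called by camera. The bipolar list had a median slope of 0.08 (adjusted p = 0.0619), with PRKCA at 0.14 ± 0.15, ISL1 at 0.07 ± 0.17 and VSX1 at 0.04 ± 0.18. Photoreceptor genes had a median of 0.05 (adjusted p = 0.214), with RXRG, the retinoid receptor of cones, at 0.20 ± 0.12, AIPL1 at 0.04 ± 0.12 and the arrestin ARR3 at 0.03 ± 0.12. Amacrine genes had 0.02 (adjusted p = 0.755), with CALB2, the calcium binding protein calretinin, at 0.22 ± 0.17, C1QL1 at 0.06 ± 0.15 and NHLH2 at -0.18 ± 0.14. Horizontal cell genes had 0.03 (adjusted p = 0.951) over LHX1 (-0.06 ± 0.11), TFAP2A (0.08 ± 0.10) and LHX5 (0.03 ± 0.07). The neurogenic list had 0.03 (adjusted p = 0.951), with BTG2 at -0.05 ± 0.15, OLIG2 at 0.04 ± 0.14 and DLL1, a Notch ligand, at 0.02 ± 0.13. In the Muller glia list (median 0.02, adjusted p = 0.767) 1 gene, VIM, fell adjusted over the list alone (adjusted p = 0.0109). Housekeeping genes had -0.04 (adjusted p = 0.301), with ACTB, ENO1 and GAPDH at 0.02 ± 0.07, -0.06 ± 0.07 and 0.01 ± 0.07. Dissociation stress genes had 0.02 (adjusted p = 0.469), with the chaperones HSP90AA1, HSPA8 and DNAJA1 at 0.03 ± 0.08, -0.08 ± 0.11 and -0.08 ± 0.16.

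Lists for cells outside the neural retina were not called either. Lens genes had a median slope of 0.03 (adjusted p = 0.426), with the crystallins CRYBA4 and CRYBB1 at 0.36 ± 0.16 and 0.03 ± 0.13 and MIP at 0.03 ± 0.11. Erythroid genes had 0.02 (adjusted p = 0.951), with ALAS1, an enzyme of heme synthesis, at 0.13 ± 0.16 and the globins HBAD and HBA1 at 0.29 ± 0.16 and 0.32 ± 0.15. The list asked for ALAS2 and not for ALAS1, which entered by a match of gene synonyms and need not mark erythroid cells. Pigment epithelium genes had 0.01 (adjusted p = 0.849), with BEST1, MLANA and MITF at -0.07 ± 0.11, 0.06 ± 0.11 and -0.02 ± 0.09. Microglia had -0.01 (adjusted p = 0.849), with CSF1R at 0.06 ± 0.11, CD74 at -0.08 ± 0.09 and C1QC at 0.02 ± 0.10. Vascular and mesenchymal genes had 0.02 (adjusted p = 0.767), with the collagen COL1A1 at -0.09 ± 0.15, ESAM at -0.04 ± 0.14 and PDGFRB at 0.05 ± 0.12. Oligodendrocyte genes had -0.05 (adjusted p = 0.426), with MBP, the myelin basic protein, at 0.16 ± 0.13, GJB1 at -0.03 ± 0.11 and CLDN11 at -0.10 ± 0.07. Median, mean and test had the same sign in the 7 called lists. Camera pointed down while median and mean were positive in the neurogenic, pigment epithelium and erythroid lists. In the Muller glia, dissociation stress and vascular lists the median was positive and the mean and test were negative. In the microglia list the mean was positive and the median and test were negative.

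From E3 to E6, cells with dividing-cell transcripts were set against cells with neuronal ones. STMN2 had a mean of 5.11 ± 0.27 at E3 (SD over 6 cells) and 16.62 ± 1.0 at E6 (SD over 10 cells). GPM6A, a neuronal membrane glycoprotein, had 5.17 ± 0.42 and 15.36 ± 0.78, SCN3B, a sodium channel subunit, 5.48 ± 0.83 and 14.71 ± 1.26, PSMC6, a proteasome subunit, 5.0 (all 6 cells at the floor) and 14.17 ± 0.85, and HMP19, a neuronal vesicle protein, 5.40 ± 0.82 and 14.46 ± 1.23. All 5 were detected in 0 of 6 E3 cells (upper limit 45.9%) and in 10 of 10 E6 cells (lower limit 69.2%). Genes of each step were picked for such shares, and the limits make no allowance for that choice. In the opposite direction, PBK, a mitotic kinase, had 13.64 ± 1.21 at E3 and 5.21 ± 0.43 at E6, HJURP 12.89 ± 2.92 and 5.35 ± 0.57, and SPAG5, a spindle protein, 10.57 ± 2.71 and 5.11 ± 0.24. NRIP1, a nuclear receptor corepressor, had 13.63 ± 1.42 and 5.16 ± 0.37, and SLC16A1, a monocarboxylate transporter, 12.88 ± 0.62 and 5.42 ± 0.90. These 5 were detected in 6 of 6 E3 cells (lower limit 54.1%) and 0 of 10 E6 cells (upper limit 30.8%).

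The cell mean over the cell cycle list was 9.79 ± 1.85 at E3 and 6.34 ± 0.60 at E6, a difference of -3.46, and over the ganglion cell list 5.95 ± 0.52 and 10.72 ± 0.39, a difference of 4.77. The synapse list differed by 1.88 and the early neuron cytoskeleton list by 4.79, with all 18 of its genes higher at E6. Among 10000 random lists, the median difference of the cell cycle list (-3.76) stood at percentile 0, the ganglion cell list (6.36) at 100, early neuron cytoskeleton (5.19) at 100 and synapse (1.63) at 99.9. The erythroid list had a median difference of -1.18 (percentile 0.2) with 8 of 9 genes lower at E6, mitochondrial respiration -0.97 (percentile 0) and ribosomal protein -0.78 (percentile 0.4). The 3′ excess of ACTB was larger in the E3 cells, 6.65 ± 1.99 against 1.95 ± 1.55, while that of GAPDH was alike, 0.64 ± 0.75 and 0.66 ± 0.91. With 1 sample per time point the differences have no replicate check.

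From E6 to E9 no list differed as widely as the cell cycle and ganglion cell lists did from E3 to E6. The cell mean of the ganglion cell list was 10.72 ± 0.39 at E6 and 10.22 ± 0.30 at E9, and that of the cell cycle list 6.34 ± 0.60 and 6.41 ± 0.42. WLS, a carrier needed for Wnt secretion, was detected in 1 of 10 E6 cells (0.3 to 44.5%) and 6 of 6 E9 cells (54.1 to 100%), with means of 5.72 ± 2.09 and 12.12 ± 1.73. TTC27 (2 of 10 and 6 of 6 cells, difference 7.41) and LETM1, a mitochondrial inner membrane protein (2 of 10 and 6 of 6, difference 5.70), were also more often detected at E9, as were CITED4, a transcriptional coactivator (0 of 10, upper limit 30.8%, and 5 of 6, difference 6.18), and ZDHHC5, a palmitoyltransferase (0 of 10 and 5 of 6, difference 0.98). MGEA5, which removes O-GlcNAc from proteins, was detected in 8 of 10 E6 cells and 0 of 6 E9 cells (upper limit 45.9%, difference -4.43). CSNK1G1, a casein kinase (difference -5.14), LMNB1, the nuclear lamin B1 (-2.95), SLC12A3 (-1.51) and the homeobox gene GBX2 (-1.36) were each detected in 9 of 10 E6 and 1 of 6 E9 cells.

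In this step the neurogenic list had a median difference of -0.86 (percentile 0.5 of random lists), housekeeping genes -0.82 (0.2) and ribosomal protein genes -0.42 (0.2). Early neuron cytoskeleton genes had -0.50 (2.6), with 13 of 18 lower at E9, and lens genes -0.80 (1.4), with 9 of 9 lower. Array background was log2 6.79 ± 1.12 at E6 (SD, n = 10) and 5.80 ± 0.28 at E9 (SD, n = 6). Means over genes were 0.08 for the cell cycle list and 0.71 for the synapse list, while their medians were negative, -0.13 and -0.06. The arrays of E6 replicate 4 and E9 replicate 3 correlated at r = 0.975, across probe sets within cells, and the next most alike pair of cells at 0.598. Both labels were kept as deposited. Without E6 replicate 4, WLS was detected in 0 of 9 E6 cells and TTC27 and LETM1 in 1 of 9 each, with differences of 7.06, 8.12 and 6.40. The naming rule would then give LMLN (difference 5.86), DOPEY2 (5.67), PRSS35 (-2.33) and C7orf62 (-1.85) in place of CITED4, ZDHHC5, SLC12A3 and GBX2.

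From E9 to E14 the cell mean of the ganglion cell list was 10.22 ± 0.30 and 10.91 ± 0.54 (median difference 0.68, percentile 98.5). CNTNAP1, a protein of the axon-glia junction, was detected in 0 of 6 E9 cells (upper limit 45.9%) and 8 of 8 E14 cells (lower limit 63.1%), with means of 5.14 ± 0.33 and 12.29 ± 2.0. PKIA, an inhibitor of protein kinase A, had 5.04 ± 0.08 and 9.83 ± 2.04, and DSCAML1, a neuronal adhesion molecule, 5.46 ± 0.45 and 7.42 ± 0.45, with the same shares of cells. PTPN12 and PLOD1 were detected in 0 of 6 and 7 of 8 cells, with differences of 3.72 and 3.49. In the opposite direction, ELMO1, a Rac regulator, had 13.64 ± 0.83 at E9 and 5.26 ± 0.43 at E14, AGO4, an Argonaute protein, 13.62 ± 0.58 and 5.25 ± 0.38, and IDH1, the cytosolic isocitrate dehydrogenase, 12.58 ± 1.15 and 5.0. YAF2 (difference -6.96) and STRAP (-6.78) behaved alike, all 5 in 6 of 6 E9 cells and 0 of 8 E14 cells (upper limit 36.9%).

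Photoreceptor genes had a median difference of 0.49 from E9 to E14 (percentile 97.7, 15 of 16 genes higher at E14) and lens genes 0.58 (percentile 97.6, 9 of 9 higher). Ribosomal protein genes, lower at the later age in both earlier steps, had 0.51 (percentile 96.2, 46 of 67 higher). Array background was higher at E14 too, with log2 6.50 ± 0.56 (SD, n = 8) against 5.80 ± 0.28 at E9 (n = 6), and most photoreceptor genes lay near the floor at both ages (PDE6G 5.52 and 6.51, OPN1LW 5.26 and 5.79). The cell cycle list had a median difference of 0.15 and a mean of -0.29, and the early neuron cytoskeleton list 0.48 and -0.63. The synapse list was lower at E14 by both, -0.13 and -0.50, with 11 of 19 genes lower. The 3′ excess of ACTB was 1.26 ± 0.54 at E9 and 3.08 ± 0.80 at E14, and that of GAPDH 0.27 ± 0.35 and 0.39 ± 0.46.

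Detection of the lists in single cells largely followed the same division. A cell of E3 had 60.1 ± 20.6% of the cell cycle genes detected (SD over 6 cells), E4 79.8 ± 9.3% and E7 87.9%, against 18.2 ± 6.9% at E6, 21.7 ± 5.2% at E9 and 20.5 ± 6.2% at E14. Ganglion cell genes were detected at 18.4 ± 7.3% at E3, 17.5 ± 8.0% at E4, 11% in the E7 cell, 64.7 ± 9.0% at E6, 62.3 ± 5.2% at E9 and 67.8 ± 6.6% at E14. The E3 cells were not alike, since replicate 5 had 21.2% of the cell cycle genes, within the range of the E6, E9 and E14 cells, and 54.5 to 75.8% were detected in the others. E5 held both kinds, with cell cycle shares of 69.7 and 66.7% in replicates 4 and 5 and 15.2, 27.3 and 9.1% in replicates 1, 2 and 3, whose ganglion cell shares were 73.7, 68.4 and 68.4%. Retinal progenitor shares were 52.6 and 68.4% in replicates 4 and 5 and 26.3, 21.1 and 36.8% in replicates 1, 2 and 3. NES did not follow this division, with 15.44, 15.15 and 6.02 in replicates 1, 2 and 3 and 14.93 and 14.68 in replicates 4 and 5. Retinal progenitor genes had 59.6 ± 8.0% at E4, 63.2% in the E7 cell and 26.8 ± 6.3% at E6. Synapse genes were highest at E9 (50 ± 12%), and housekeeping genes lay between 75 ± 17.7% at E15 and 94.8 ± 4.7% at E9.

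**Figure D2:**
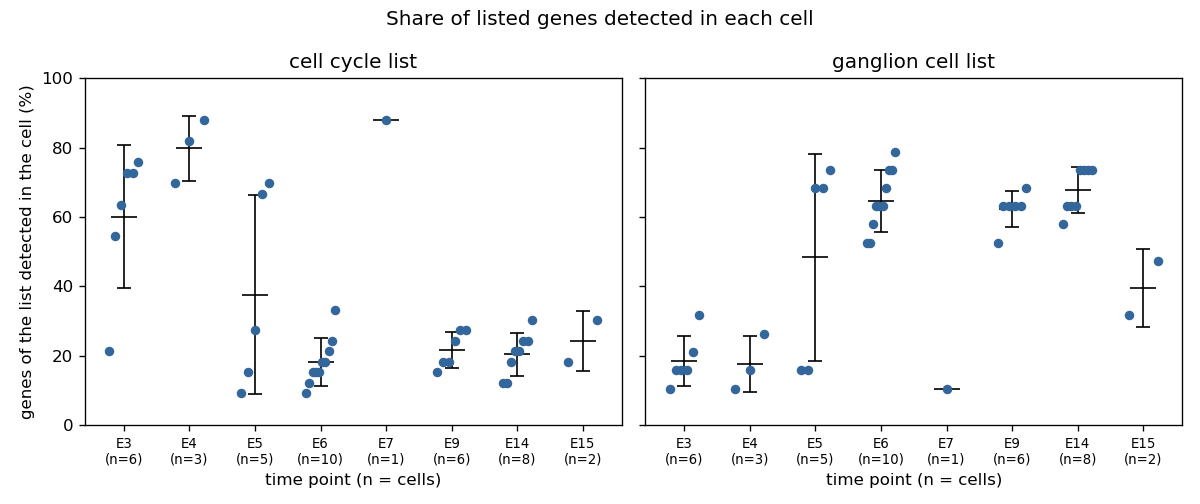
Percent of the genes of the cell cycle list (left) and the ganglion cell list (right) detected in each cell (points) by time point, with bars for the mean and 1 SD over cells. E6 cells average 18.2% of cell cycle and 64.7% of ganglion cell genes, and E3 cells 60.1% and 18.4%.

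Clustering placed the cells largely by age. Cluster 1 was cycling-cell-like, with 9 cell cycle markers among its leading genes, and held 6 of 6 E3 cells (54.1 to 100%), 3 of 3 E4 cells, 2 of 5 E5 cells (5.3 to 85.3%) and the E7 cell; PBK, PTTG2, NES, CKS1B and RACGAP1 led it. The other 3 E5 cells formed cluster 2, led by PPP1R1C, BET1, AMY1A, ICA1 and FAM76B and left unnamed. Cluster 3 was ganglion-cell-like by EBF3, STMN2 and CHRNB3 and held 10 of 10 E6 cells (69.2 to 100%) and 6 of 6 E9 cells, with FGFR3, IDH1, STMN3, AGO4 and KIF21A in front. The 8 E14 cells made up cluster 4 (63.1 to 100%), led by ENO2, MAT2B, HS3ST2, RPH3A and FAM49A. Each E15 cell stood alone, replicate 3 in cluster 5 (GRID2IP, ZNF804B, ATP6V0D2, EIF2B4, ZIC1) and replicate 2 in cluster 6 (GNB3, OIT3, ATP6V0D2, ZNF804B, TLL1). Ganglion cell genes were detected at 63.8 ± 7.7% in the cells of cluster 3 (SD), 70.2 ± 3.0% in cluster 2 and 67.8 ± 6.6% in cluster 4. The name therefore does not set cluster 3 apart from these 2 clusters. The name of cluster 3 was lost without the arrays of high background, without E6 replicate 4 and E9 replicate 3, and with 8 clusters. A cluster of a single time point may reflect that sample and not a cell type.

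Cells of the same time point were on average more alike than cells of different ones. The mean Pearson correlation was 0.457 ± 0.075 over 117 pairs (SD) against 0.348 ± 0.099 over 703 pairs. Correlations are across probe sets, which are not independent replicates. The E9 cells were the most alike (0.552 ± 0.014), followed by E14 (0.490 ± 0.042), E4 (0.453 ± 0.027), E3 (0.448 ± 0.051), E6 (0.431 ± 0.068) and E5 (0.385 ± 0.052). The 2 E15 cells correlated at 0.153 with each other, and at 0.154 ± 0.017 with E14 cells, both on arrays of high background. The average did not hold at each age: E6 cells were closer to E9 cells (0.476 ± 0.096) than to each other (0.431 ± 0.068) or to E3 cells (0.302 ± 0.046). The E6 with E9 mean includes the pair of E6 replicate 4 and E9 replicate 3 at 0.975, which raises its mean and SD. All 3 means include E6 replicate 7, on an array of high background. The cycling E5 cells correlated at 0.430 ± 0.036 with E3 and 0.304 ± 0.038 with E6, and the other E5 cells at 0.364 ± 0.036 and 0.371 ± 0.044.

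**Figure D3:**
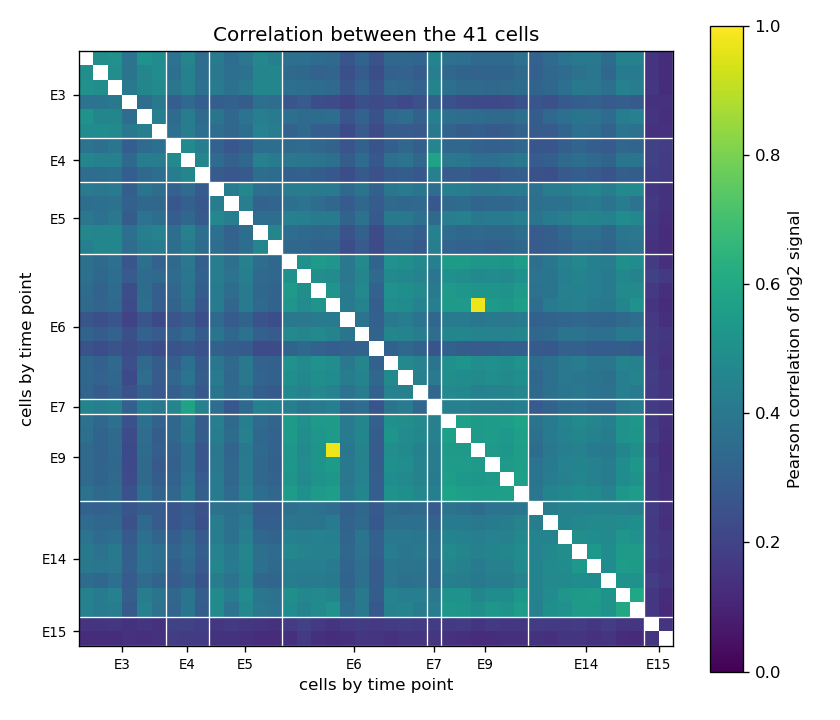
Pearson correlation of floored log2 signal (colour scale from 0 to 1) between all pairs of the 41 cells, ordered by time point on both axes, with white lines between time points and a blank diagonal. The bright pair off the diagonal is E6 replicate 4 with E9 replicate 3 (0.975), and the dark band is the E15 cells.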

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

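The tests of the shared profile and of array background were chosen after the results were seen, as were the HINTW level of 10 and the level of 13, both in log2. The test of the other W-linked genes was written before its result was seen. In 135 groups of 5 to 10 cells, 20 values stood apart from the other cells of their time point by a gap that is large against the range of the group. Chance flags about 1 in 20 groups of continuous values. Many flagged values are shares of short lists with ties, where detection of 1 gene can make a flag. The 20 flags therefore cannot be set against that rate.

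Among shares of listed genes detected, retinal progenitor genes stood at 26.3% in E3 replicate 6, below the other E3 cells, at 36.8% in E9 replicate 2 and at 47.4% in E14 replicate 3, above their groups. Ganglion cell genes were low in E9 replicate 6 (52.6%). Horizontal cell genes were high in E6 replicate 7 (40.0%) and E9 replicate 4 (20%). Photoreceptor genes were low in E5 replicate 4 (10.3%), a cell with 69.7% of the cell cycle genes. Early neuron cytoskeleton genes were high in E3 replicate 3 (63.2%). Dissociation stress genes were low in E9 replicate 1 (30.8%), and lens genes in E14 replicate 8 (15.4%). Pigment epithelium genes were at 0% in E5 replicate 2, where the nearest cell had 14.3%. Oligodendrocyte genes were low in E5 replicate 5 (14.3%) and E9 replicate 4 (0%).

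Among array measures, E6 replicate 7 stood above the other E6 arrays in median signal (log2 7.38) and in background (log2 9.67). The 3′ minus 5′ difference of GAPDH, a glycolytic enzyme, was high in E5 replicate 1 (0.93) and E9 replicate 4 (0.95). E3 replicate 4 was unlike the other cells, its highest correlation with any cell being 0.405.

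The 689 probe sets designed on other sequence records were kept in the pool for the slope test, the clusters and the correlations. The brightest of them reached 13 or more in 19 of 41 cells, namely 3 at E3, 1 at E5, 5 at E6, 4 at E9 and 6 at E14. Only 2 of the 689 reached that level in any cell, and the identity of the sequence was not analysed here.

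E6 replicate 4 and E9 replicate 3 had their highest correlation, 0.975, with each other, and the next most alike pair had 0.598. That gap argues against different cells of a common kind. Of the probe sets detected in either array 77.3% were detected in both, against at most 43.4% in any other pair, while 0 values were equal and the 4216 probe sets above log2 10 in both differed with an SD of 0.56. This is consistent with cDNA of the same cell on both arrays, as a hypothesis. Which label is right stays open. E6 replicate 4 correlated at 0.542 with the other E9 cells and at 0.455 with the other E6 cells. However, E6 replicate 1 correlated at 0.538 with these E9 cells, and E6 cells on average were closer to E9 cells than to each other.

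The brighter of 2 HINTW probe sets, for a gene of the W chromosome that only female birds carry, reached log2 10 or more in 14 cells: 6 of 6 at E3, 5 of 5 at E5, the E7 cell and 2 of 2 at E15, with 0 cells at E4, E6, E9 or E14. The other HINTW probe set reached that level in only 8 of these 14 cells and in no other cell, with 5 of 6 at E3 (1.7 in replicate 4), 1 of 5 at E5 (13.8, the others 2.1 to 6.1), the E7 cell and 1 of 2 at E15 (5.3 in replicate 3), so the division by time point rests on 1 probe set. Of the 14 cells 14.3% were on arrays of high background, namely the 2 at E15. No E3, E5 or E7 array was of that kind, so high background is not the source at these ages. At E15 the background was log2 9.97 in replicate 2 and 10.25 in replicate 3, against HINTW at 15.5 and 11.2. The value of replicate 3 thus lay near its background. The 12 other W-linked genes had a median difference of 0.28, at percentile 90.3 of random lists, which does not reach the bound of 95 set beforehand. That bound was judged unsuitable only after the result was seen, since members went both ways and most lay near the floor. LOC430910 (difference 5.56) was detected in 9 of the 14 cells with high HINTW and 0 of the 27 others. NEDD4L (-2.14) was detected in 6 of the 14 and 18 of the 27. Whether the sex of the embryos could account for the division stays open.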

How the results depend on the processing

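Alternatives without the arrays of high background or the pair with a shared profile, with the floor at the highest background and with detection as the response were chosen after seeing the data. The count of 33 probe sets was 0 in limma with no floor (860 rising and 240 falling at an unadjusted p under 0.05), after quantile normalization (1051 and 607), after scaling to a common 75th percentile (1039 and 538), with equal weights (1351 and 271), without the arrays of high background (1400 and 341), with a floor at the highest background (1133 and 279) and with detection as the response (781 and 553). It was 2 with a floor at the 25th percentile, 55 with no filter, 76 on log2 of day (75 rising), 12 for late against early ages, 53 with E6 replicate 1 moved to E5 and 82 without the 2 cells of later accession. Time points left out in turn gave 0 (without E4, 1048 and 192) to 104 (without E6, 94 rising) and single cells 16 to 70, with 11 cells moving it over 1.5 times; the cause was not tested. The replicate block gave 8. Replicate numbers do not pair the cells: the 85 pairs with the same number had a mean correlation of deviations of -0.004 (-0.14 to 0.03), and 3 of 38 cells correlated best with their own number.

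All 792 slopes of the 12 named rising genes under 66 settings stayed positive, and their calls held in 38 to 55 of them. These genes were chosen for their slope on the same cells, and most settings left out only a cell or a time point. A positive sign was thus favoured in advance and is no independent check. Called lists numbered 7, 3 with detection as the response and 0 with an estimated correlation. Over all settings 32 single list results lost a call, 22 gained one and 1 reversed, among them gains for the photoreceptor and housekeeping lists with equal weights and without E14. The cell cycle, ganglion cell, synapse and ribosomal protein lists were called in all 49 fits with a time point or cell left out, but their median slopes ranged widely: -0.366 to -0.192, 0.0978 (without E3) to 0.419 (without E15), 0.0549 (without E15) to 0.219 (without E14) and -0.102 to -0.0521. With the floor at the highest background the first 3 had -0.122, 0.0919 and 0.0075. The erythroid list, not called, turned from down to up without E3 (median slope 0.0476, adjusted p = 0.0115; median slopes over these fits -0.0309 to 0.0476), and the bipolar list was called in 14 of the 49 (adjusted p 0.0136 to 0.664). The ganglion cell difference from E3 to E6 was 4.27 after quantile normalization and 5.61 with no floor. Detection at the 70th and 90th percentile gave 31.2 and 11.2% for cell cycle genes at E6, 28.9 and 7.9% for ganglion cell genes at E3, and 74.2 and 54.2% at E6. Cells in ganglion-cell-like clusters numbered 16, and 27 with 4 clusters, 0 with 8, 0 without the arrays of high background and 0 without the pair that shares a profile. Spearman correlation gave 0.303 within and 0.222 between time points. The cause was not tested, except that another detection level moves detection by construction. The share of probe sets above background was lowest on the E15 arrays (12.4 and 11.2%) and E6 replicate 7 (12.4%), which limits low genes there.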

Other observations

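The tests of the rising probe sets were chosen after the result was seen, and the genes of the next 2 paragraphs were chosen after their values were seen; these values have no test. FABP7, a fatty acid binding protein of neural progenitors, averaged log2 15.53 ± 1.22 in the 3 E4 cells (SD) and 14.94 in the E7 cell, and was detected in 0 of 6 E3 cells (upper limit 45.9%) and 0 of 5 E5 cells (upper limit 52.2%); at E6 it was detected in 4 of 10 cells (8.20 ± 3.50) and at E9 in 1 of 6. HES5, a Notch target, averaged 15.53 ± 1.06 at E4, 14.82 in the E7 cell and 5.65 ± 0.83 at E3, and CCND1 (cyclin D1) 12.83 ± 0.32, 12.31 and 7.67 ± 4.12. PAX6 was detected in 3 of 6 E3 cells (11.8 to 88.2%) and in 3 of 3, 5 of 5, 10 of 10, 6 of 6 and 8 of 8 cells at E4, E5, E6, E9 and E14, but in 1 of 2 at E15 (9.07 ± 0.82). The transcription factor NHLH2 was detected in 10 of 10 E6 cells, 2 of 6 E9 cells and 2 of 8 E14 cells, with means of 11.76 ± 2.62, 6.78 ± 2.46 and 6.19 ± 1.75, and ISL1 in 8 of 10, 3 of 6 and 3 of 8. EBF3 averaged 15.85 ± 0.75, 13.96 ± 0.88 and 13.14 ± 3.42. SYT1, a calcium sensor of vesicle release, was detected in 7 of 10 E6 cells, 6 of 6 E9 cells and 1 of 8 E14 cells.

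Both E15 cells are on arrays of high background (log2 9.97 and 10.25) and differ from each other. In them VSX1, a bipolar transcription factor, averaged 17.61 ± 0.56 (SD, n = 2), CPLX3 15.91 ± 1.38 and OTX2 12.23 ± 2.27. Replicate 2 had 72.7% of the bipolar, 60% of the horizontal, 47.4% of the ganglion cell and 27.6% of the photoreceptor list detected, and replicate 3 had 27.3, 20, 31.6 and 37.9%; E14 cells averaged 30.7 ± 15.3% of the bipolar list. VSX1 was also at 14.89 in the E7 cell and at 5.26 ± 0.74 in the E14 cells. NEFL, a neurofilament subunit, was detected in 0 of 2 E15 cells (upper limit 84.2%) and 8 of 8 E14 cells (16.11 ± 0.55). Globin transcripts reached log2 13 or more in some cells: HBA1 in 3 of 6 E3 cells, 4 of 8 E14 cells and 1 of 2 E15 cells, HBAD in 2, 5 and 1, and the embryonic globins HBZ and HBE in 2 of 6 E3 cells each. At other ages HBZ was highest in E4 replicate 1, at 12.8, just under this level.

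The 33 probe sets that rose with day had a median slope of 0.61 (SD over probe sets 0.13). Chance cannot be excluded: 18 of 100 orders of the 8 days, the real order included, called as many. The highest other order called 533, and the source of those calls was not tested. Without the 6 arrays of high background the median slope was 0.69 (SD 0.14) with 33 of 33 positive. The calls ended in that fit of 6 time points with 4 residual degrees of freedom. The probe sets had been chosen for their slope on data that include the remaining arrays. A positive slope was thus favoured in advance, and these values cannot decide on background. The median difference of the 33 between E14 and E6, where cell cycle genes were seldom detected at either age, was 5.16 (SD 1.63, lowest 0.04). Selection by slope on the same means favoured a large difference in advance. It therefore cannot decide whether a replacement of cycling cells by neurons was the source. Maturation of neurons with age may account for the slopes and stays open, untested, beside differences between the unnamed embryos.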
